A study of Mus musculus with 18 samples.

How the data were processed

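The libraries were made from liver of C57BL/6 mice that was flash-frozen in liquid nitrogen, per the labels' protocols, with RNA taken up in TRIZOL, treated with DNase I, enriched for poly(A) with oligo(dT) beads and broken to fragments, followed by random-hexamer priming and PCR. Per the labels, RNA of 3 mice was pooled for each library, and 2 pools stood for each of the 9 groups. The sham group is labelled only as a control, so its time of collection is not known here, and the sex of the mice is not in the labels. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool and the strand are not given in the sources used here.

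Each deposited table held 1 library. Per the file headers, the read count of a gene is the number of reads mapped uniquely to it, and the header gives the library's total. The deposited RPKM values are counts divided by gene length and header total; recomputed from the count columns they matched within 0.0001. In 16 tables the listed counts summed to the header total, so that an unlisted gene had 0 reads. In the other 2 the listed counts stopped short of the total, so that an unlisted gene there is unknown up to a bound of 6.52 CPM for sham replicate 2 and 19.0 CPM for 0.5 h replicate 1. Tables listed 17180 genes in all, of which 17130 matched a gene name by identifier. For 45 symbols that occurred more than once the identifier kept the genes apart. Genes without a name held at most 0.0326% of the reads of a library.

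Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, 1 fit of all groups, contrasts of the groups compared), and p-values were adjusted by Benjamini-Hochberg within each contrast at a false discovery threshold of 0.05. The test, the comparisons, the gene lists, the rule for naming genes and all but the added alternatives were fixed before the data were examined. In 18 libraries the genes listed in both short tables were tested, 4906 in number, with 9 residual degrees of freedom, a biological coefficient of variation of 0.139 and TMM factors from 0.765 to 1.16. In the 16 complete libraries 12199 genes were tested, with 7 residual degrees of freedom, a coefficient of 0.166 and factors from 0.776 to 1.18; this second test was added after the tables had been seen to end early. A gene was kept if it had the CPM that 10 reads make in the median library in at least 2 libraries and 15 reads in total. Log2 CPM values, as used for the gene list tests, limma-trend and differences between libraries, had a prior count of 2. The log2 fold changes of edgeR were fitted at its default prior count. The quasi-likelihood test gives no SE, so the SE was taken as the absolute log2 fold change divided by the root of the F statistic. It holds no information beyond that test and is less reliable for genes with few reads in a group.

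Gene lists, 35 in number with 583 entries, of which 8 had no match, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, for lists with at least 3 measured genes, and again with an estimated correlation. This gave 208 list tests in 18 libraries and 272 in the 16. Named genes were chosen by rule: the 6 largest rises and the 6 largest falls among the genes called against sham, and 3 and 3 between times, with a mean of at least 10 CPM and both libraries of a group on the same side of both reference libraries. Unnamed gene models were left out, and some genes that the rule names are not reported here. From a gene list at most 4 members were named, smallest p first. The self-test used simulated counts with 200 changed genes and the same dispersion, 0.02, for every gene. Squared, the coefficient of 0.166 in the 16 libraries lies above that, so recovery there is likely overstated. At 48 h against sham in 18 libraries the self-test recovered 92% of 2-fold and 100% of 4-fold changes, with 7 false calls of 199. With 2 libraries against 1 over 12199 genes it recovered 30% and 89%, with 5 false calls of 124.

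Alternatives tried were DESeq2 1.42.0, RLE factors, limma-trend on log2 CPM and on log2(RPKM + 1), no filter and only the 2 groups compared. Others were unlisted genes taken as 0, a block for the replicate number, the rotation test fry and leaving out each library in turn. Calls with an estimated change of at least 2-fold were also counted, without a test against that change. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. Totals of 7.78 to 9.16 in units of 1000000 reads make 3 reads, the floor used for a gene with 0, at most 0.386 CPM. Such floors and the 95% limits cover counting error only, since PCR reads are not independent molecules.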

Results

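Liver RNA of C57BL/6 mice was sequenced at 0.5, 2, 4, 24, 48, 72, 120 and 168 h after 2/3 partial hepatectomy, an operation after which the remaining lobes grow back, and after a sham operation. The 9 groups held 2 libraries each, 18 in all, and each library was a pool of RNA from 3 mice, so that n = 2 pools per group below and 54 mice in total. Each deposited table gave the reads mapped uniquely to each gene, and the totals, in units of 1000000 reads, ran from 7.78 to 9.16 per library. In 16 libraries the table was complete and listed 14050 to 14741 genes. The table of sham replicate 2 ended after 8026 genes at a count of 52, which left 1.14% of its reads unlisted, and that of 0.5 h replicate 1 ended after 4908 genes at a count of 157, which left 4.73% unlisted. Changes were therefore tested in all 18 libraries over the 4906 genes listed in both short tables, and, after the tables had been seen to end early, in the 16 complete libraries over 12199 genes. In the 16-library test the sham group and the 0.5 h group had 1 library each, which was assumed to vary like the other groups. Rises called there against sham were also set beside sham replicate 2. Nearly all that are not said below to lie above its value or bound were unlisted in it and did not exceed the bound. Those cannot be judged, and at most 4 rises at any 1 time lay at or below its listed value. Genes scarce in sham and abundant later, among them most genes of cell division, were measured in the 16-library test alone. The 18-library test thus leaves out genes that rise from a low start but keeps genes that fall to a low level. Its balance of higher and lower calls and its counts of peaks are therefore not those of all genes.

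Levels are given as CPM (counts per 1000000 reads) after TMM scaling, as the mean ± SD of the pools, and changes as log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p. The p-values measure the spread between pools of 3 mice, not between single mice. That spread is estimated over all 9 groups of a fit, so groups outside a comparison enter its p-values. With only the 2 groups compared in the fit, the 18-library calls against sham went from 282 to 1021 at 168 h and from 850 to 354 at 24 h. Few calls at a time therefore do not by themselves show a return to sham. In the counts for gene lists, a gene that did neither did not pass the test. Between the pools of a group, the SD of the log2 differences across 4906 genes lay between 0.242 in sham and 0.390 at 24 h. Albumin, the main plasma protein of the liver, took 5.40% to 13.5% of the reads of a library. When libraries were scaled by their totals alone, the median gene of the 18-library test moved by -0.17 at 2 h, -0.37 at 4 h, 0.10 at 24 h and 0.15 at 48 h against sham, and with TMM it lay between -0.02 and 0.02, so that changes are relative to that median. By totals alone it moved by -0.16 from 0.5 to 2 h, -0.20 from 2 to 4 h, 0.47 from 4 to 24 h, -0.10 from 72 to 120 h and -0.17 from 48 to 168 h. Strand is not given in the sources used here, so reads of overlapping exons cannot be assigned: among the genes named below this holds for Abcb11, Acot3, Acss2, Apoa4, Apoc2, Arntl, Ccnd1, Cd74, Cdc20, Cdkn1a, Cebpa, Col3a1, Col4a1, Col4a2, Cyp2d9, Cyp2f2, Cyp51, Dbp, Dusp1, Elovl3, Fgg, Foxm1, Gls2, Hsd3b7, Idi1, Irf7, Jun, Lig1, Lss, Mid1ip1, Mt2, Nop56, Nr1d1, Pkm, Plk1, Prc1, Sds, Serpina3m, Slc25a25, Syt12, Tef, Tifa, Tiparp, Top2a, Ube2s and Wdr92. Members of the Mup, Saa, Orm, Mt, Serpina3, Gstm, H2, Hba and Cyp families share sequence, and the split of reads within each family is uncertain.

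Over the whole course, 3366 of the 4906 genes differed among the 9 groups in the 18-library test, and 5220 of the 12199 genes in the 16-library test. Of the 3366 genes, 939 had their highest group mean at 4 h and 916 their lowest. At 48 h 634 genes peaked and 531 were at their lowest, and at 168 h the numbers were 363 and 394.

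**Figure D1:**
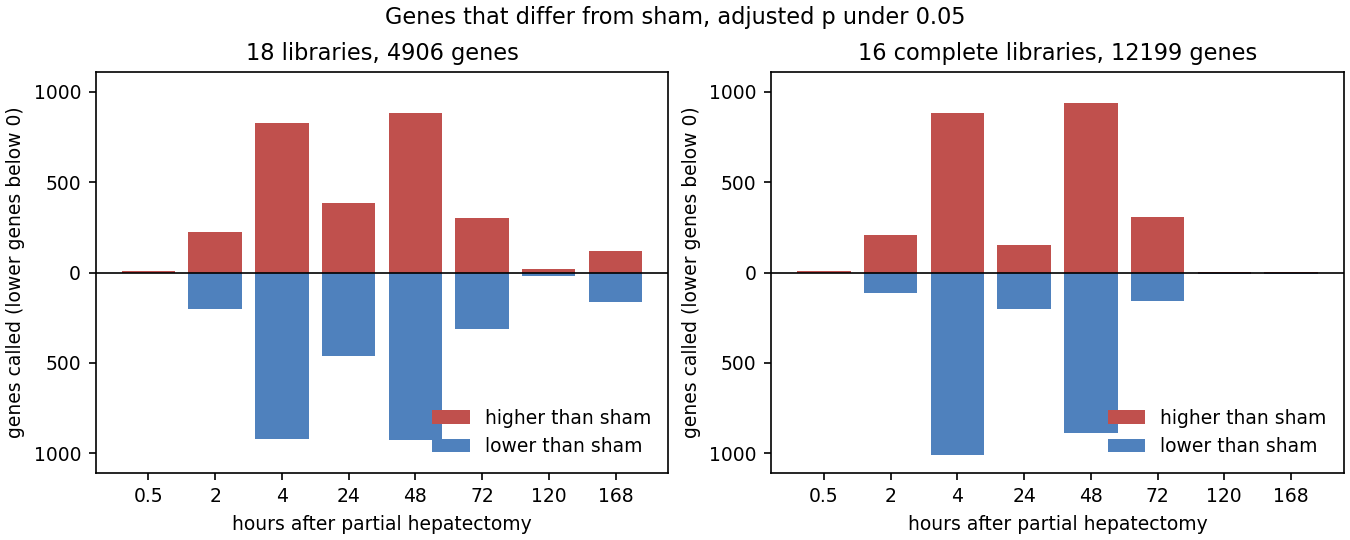
Number of genes called higher (upward bars) and lower (downward bars) at each time against sham, in the 18-library test over 4906 genes and in the 16-library test over 12199 genes. Calls reached 829 higher and 920 lower at 4 h and 881 higher and 925 lower at 48 h in the 18-library test. The 4906 genes leave out those scarce in sham replicate 2 or 0.5 h replicate 1, so this balance is not that of all genes.

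The comparison of 0.5 h with sham asked which transcripts had moved within the first sampled interval after resection. Dusp1, a phosphatase that switches off MAP kinases, rose from 25.0 ± 2.25 to 161 ± 64.6 CPM (log2 2.69 ± 0.27, adjusted p = 0.000396; gene 19252, chromosome 17, 26505591 to 26508472). Jun, a transcription factor subunit of AP-1, rose from 26.2 ± 2.52 to 89.0 ± 16.6 CPM (log2 1.77 ± 0.15, adjusted p = 9.41e-05; gene 16476, chromosome 4, 95049036 to 95052222). Also higher were Slc25a25 (1.70 ± 0.28), a mitochondrial carrier, Btg2 (1.55 ± 0.27), an inhibitor of proliferation, the kinase gene Pim3 (1.42 ± 0.25) and Gdf15 (1.38 ± 0.24), a stress-induced cytokine. The genes that fell were Kpna4, a nuclear import receptor (log2 -1.08 ± 0.17, adjusted p = 0.0239), and Antxr2 (log2 -0.76 ± 0.12, adjusted p = 0.0239). Of the 10 immediate early genes measured in 18 libraries, 3 rose, 0 fell and 7 did neither (5 and 0 adjusted over the list alone), and the list median was 0.87. The immediate early list had camera adjusted p = 5.50e-08 and adjusted p = 0.555 with an estimated correlation. Among the 22 measured in 16 libraries, 3 rose, 0 fell and 19 did neither (11 and 0 adjusted over the list alone), with Klf2, a transcription factor of flow-exposed endothelium, at 1.98 ± 0.31. Among 8 erythroid genes, 0 rose, 0 fell and 8 did neither (5 and 0 adjusted over the list alone), and Hba-a1 (1.62 ± 0.30) had adjusted p = 0.135. The erythroid list had camera adjusted p = 2.00e-06 and adjusted p = 0.466 with an estimated correlation.

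In all, 8 genes were higher and 2 lower at 0.5 h by edgeR in 18 libraries, and 6 and 0 in 16 libraries, where 1 library stood against 1. DESeq2 split nearly evenly in 18 libraries, with 68 higher and 59 lower, and gave 19 and 1 in 16. In the 18-library test the 10 calls became 4 without sham replicate 1, 3 without sham replicate 2, 3 without 0.5 h replicate 2 and 6 without 48 h replicate 2.

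At 2 h against sham, some members of the acute phase, gluconeogenesis and cytokine lists were higher. Igfbp1, a secreted binder of insulin-like growth factors, rose from 216 ± 55.5 to 1708 ± 287 CPM (log2 2.98 ± 0.45, adjusted p = 0.00098). Steap4, a metalloreductase, rose from 196 ± 28.8 to 2280.3 ± 822 CPM (log2 3.54 ± 0.75, adjusted p = 0.00962), and Rcan1, an inhibitor of calcineurin, rose by 2.53 ± 0.16, adjusted p = 2.51e-06. Tifa (3.31 ± 0.84), Hmox1 (2.68 ± 0.45), the haem oxygenase, and Gpcpd1 (2.56 ± 0.32) were also higher. Hhex, a homeobox factor of liver development, fell from 97.4 ± 26.8 to 5.12 ± 1.42 CPM (log2 -4.25 ± 0.43, adjusted p = 8.56e-05). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 115 ± 43.1 to 15.5 ± 7.02 CPM (log2 -2.90 ± 0.71, adjusted p = 0.02; gene 13122, chromosome 4, 6265612 to 6275632), and its repressor Nr0b2 was lower too (-2.39 ± 0.64), as were Arrdc3 (-3.73 ± 0.32), Cited2 (-2.52 ± 0.28) and Paqr7 (-2.06 ± 0.31). Genes scarce in sham that rose in 16 libraries were Mfsd2a (4.76 ± 0.59), Arid5a (4.29 ± 0.69), Inhbb (3.91 ± 0.65) and Pdk4, a kinase that restrains glucose oxidation (4.42 ± 0.48).

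By list at 2 h, of 23 acute phase genes 7 rose, 0 fell and 16 did neither (11 and 0 adjusted over the list alone), with median 1.08, among them Serpina3m (1.62 ± 0.25), Fgb (1.17 ± 0.24) and Fgg (1.08 ± 0.22). The acute phase list had camera adjusted p = 8.89e-08 and adjusted p = 0.576 with an estimated correlation. Of 11 gluconeogenesis genes 5 rose, 0 fell and 6 did neither (7 and 0 adjusted over the list alone), led by Tat (1.40 ± 0.19), Got1 (1.35 ± 0.25) and Sds (1.40 ± 0.35). The gluconeogenesis list had camera adjusted p = 0.000427 and adjusted p = 0.555 with an estimated correlation. Immediate early genes went both ways in 18 libraries: of 10, 5 rose, 1 fell and 4 did neither (7 and 2 adjusted over the list alone), with Btg2 (1.97 ± 0.27) higher and Ier2 (-1.32 ± 0.30) lower. In 16 libraries 16 cytokine and NF-kB targets were measured, of which 3 rose, 0 fell and 13 did neither (3 and 0 adjusted over the list alone); these were Nfkbia, the inhibitor of NF-kB (1.26 ± 0.25), Il1r1 (2.18 ± 0.44) and Tnfaip3 (3.73 ± 0.79). The cytokine list had camera adjusted p = 9.03e-06 and adjusted p = 0.621 with an estimated correlation. Among 15 genes of fatty acid oxidation and PPARalpha, 4 rose, 0 fell and 11 did neither (6 and 0 adjusted over the list alone), with Plin2 (1.04 ± 0.18) higher. Neutrophil and monocyte markers, 13 genes, had a median of 1.07, or 0.85 with the 2 members at 0 sham reads set to the bound of 3 reads, and 0 of them passed edgeR's test by gene. The neutrophil list had camera adjusted p = 0.0306 and adjusted p = 0.774 with an estimated correlation.

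edgeR called 226 genes higher and 204 lower at 2 h in 18 libraries, and 210 and 113 in 16 libraries. Of these 210, 205 also lay above the value or the upper bound of sham replicate 2. The 430 calls became 174 without sham replicate 1, 214 without sham replicate 2, 258 without 2 h replicate 1 and 207 without 2 h replicate 2. The 323 of 16 libraries became 126 without 2 h replicate 2. The test on log2(RPKM + 1), which scales by totals alone, called 167 higher and 453 lower.

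By 4 h most acute phase genes of the liver stood above sham, and 4 h held the highest number of peaks. Lcn2, an iron-sequestering acute phase protein, went from 367 ± 402 to 4791 ± 1544 CPM (log2 3.71 ± 1.13, adjusted p = 0.0212); the sham pools themselves differed, at 83.4 and 651 CPM. For Mt1, a metallothionein, the sham pools were at 62.0 and 389 CPM, and the change at 4 h was 4.15 ± 1.06, adjusted p = 0.00833. Tifa, an adaptor of NF-kB signalling (5.54 ± 0.91), Steap4 (4.95 ± 0.80), Mt2 (4.49 ± 1.11) and Wdr92 (4.26 ± 0.31, an exon of which overlaps Ppp3r1 on the same strand) made up the other genes with the largest rises. Cyp7a1 stood at 5.73 ± 0.331 CPM (log2 -4.33 ± 0.81, adjusted p = 0.00109), and Hsd3b5, a male-biased steroid dehydrogenase, fell from 232 ± 38.6 to 15.8 ± 0.033 CPM (log2 -3.87 ± 0.58, adjusted p = 0.000218). Sdr9c7 (-3.08 ± 0.42), the replication factor gene Mcm10 (-2.99 ± 0.53), Mid1ip1 (-2.95 ± 0.31) and Arrdc3 (-2.95 ± 0.31) were lower as well. In 16 libraries Il1rn, the interleukin-1 receptor antagonist, rose by 6.48 ± 1.81, adjusted p = 0.0281, and Syt12 (7.21 ± 0.71) was also higher.

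Of 23 acute phase genes at 4 h, 20 rose, 0 fell and 3 did neither (21 and 0 adjusted over the list alone); the median was 2.16, and the fibrinogen chains Fga, Fgb and Fgg rose by 2.08 ± 0.27, 2.02 ± 0.25 and 2.11 ± 0.23. The acute phase list had camera adjusted p = 9.22e-10 and adjusted p = 0.555 with an estimated correlation. Of 12 ribosome biogenesis genes 8 rose, 0 fell and 4 did neither (8 and 0 adjusted over the list alone), with Ddx21 (1.25 ± 0.13), Nop56 (0.86 ± 0.13) and Nop2 (1.03 ± 0.17). The ribosome biogenesis list had camera adjusted p = 0.00582 and adjusted p = 0.555 with an estimated correlation. Of 18 bile acid genes 0 rose, 6 fell and 12 did neither (0 and 6 adjusted over the list alone), including the export pump gene Abcb11 (-0.58 ± 0.14) and Hsd3b7 (-0.82 ± 0.14). The bile acid list had camera adjusted p = 0.0131 and adjusted p = 0.555 with an estimated correlation. Of 16 cytochrome P450 genes 4 rose, 8 fell and 4 did neither (5 and 9 adjusted over the list alone), with Por (1.54 ± 0.18) and Cyp3a13 (0.95 ± 0.15) higher and Cyp2c50 (-0.90 ± 0.18) lower. Here and below these are the genes of a list of P450 drug metabolism, in which Por is not itself a P450. Of 14 male-biased genes 0 rose, 8 fell and 6 did neither (0 and 8 adjusted over the list alone), with Elovl3 (-2.12 ± 0.44) and Selenbp2 (-1.96 ± 0.47). The male-biased list had camera adjusted p = 0.00717 and adjusted p = 0.776 with an estimated correlation. Of 16 circadian clock genes in 16 libraries 1 rose, 8 fell and 7 did neither (2 and 9 adjusted over the list alone), with Tef (-2.12 ± 0.21), Hlf (-1.50 ± 0.23) and Cry1 (-1.58 ± 0.29) lower. The clock list had camera adjusted p = 0.000815 and adjusted p = 0.466 with an estimated correlation. The labels give no time of collection for sham, so neither the counts of clock genes nor other changes against sham separate resection from time of day. For clock genes the same holds between 4 and 24 h. Glycolysis and glucose use split: of 11 genes 4 rose, 4 fell and 3 did neither (4 and 4 adjusted over the list alone), lactate dehydrogenase Ldha (1.32 ± 0.15) and Pfkfb3 (2.37 ± 0.27) up, and the transporter gene Slc2a2 (-1.38 ± 0.17) down. Of 9 heat shock genes 1 rose, 2 fell and 6 did neither (1 and 3 adjusted over the list alone). Of 11 genes of the ER stress response 1 rose, 2 fell and 8 did neither (1 and 2 adjusted over the list alone), with Atf4 (0.93 ± 0.18) higher and Herpud1 (-1.93 ± 0.25) lower. Of 13 neutrophil and monocyte markers in 16 libraries 1 rose, 0 fell and 12 did neither (5 and 0 adjusted over the list alone), with the chemokine receptor Cxcr2 (1.50 ± 0.39) higher. The neutrophil list had camera adjusted p = 0.00258 and adjusted p = 0.763 with an estimated correlation. Their median was 3.07, or 2.61 with the 2 members at 0 sham reads set to the bound of 3 reads.

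edgeR called 829 genes higher and 920 lower at 4 h in 18 libraries and 881 and 1007 in 16. Of these 881, 796 lay above sham replicate 2's value or bound. The 1749 calls became 1116 without sham replicate 1 and 1156 without sham replicate 2. The 1888 of 16 libraries became 1125 without 4 h replicate 1. Scaled by totals alone on log2(RPKM + 1), 324 were higher and 2314 lower.

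At 24 h some replication genes had risen and some lipid synthesis genes had fallen. Ccnd1, the cyclin of G1 progression, rose from 36.2 ± 5.08 to 140.1 ± 7.14 CPM (log2 1.95 ± 0.28, adjusted p = 0.000771; gene 12443, chromosome 7, 144929931 to 144939831). Marco, a macrophage scavenger receptor, went from 18.5 ± 5.37 to 291 ± 233 CPM (log2 3.98 ± 0.61, adjusted p = 0.00117). Apoa4 (3.47 ± 0.56), Gstm3 (2.42 ± 0.69), Apcs (2.12 ± 0.51) and Lhpp (1.77 ± 0.19) were also higher. Thrsp, an inducer of lipogenesis, fell from 406 ± 56.8 to 44.4 ± 7.03 CPM (log2 -3.19 ± 0.38, adjusted p = 0.000252), and so did Selenbp2 (-4.48 ± 0.53), Upp2 (-3.71 ± 0.36), Egr1 (-3.54 ± 0.48), Lpin1 (-3.17 ± 0.49) and Car3 (-3.08 ± 0.59). In 16 libraries the PPARalpha target Cyp4a14 rose from 6.73 to 643 ± 553 CPM (log2 6.58 ± 1.43, adjusted p = 0.03), and Cyp1a1 (6.16 ± 1.54), an enzyme induced by the aryl hydrocarbon receptor, was higher.

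Of 31 genes of G1/S and DNA replication in 16 libraries 15 rose, 0 fell and 16 did neither (27 and 0 adjusted over the list alone), with median 1.80; DNA ligase Lig1 (2.81 ± 0.37), Mcm5 (2.90 ± 0.43), Mcm6 (2.52 ± 0.37) and Rrm1 (1.77 ± 0.32) were among them. The G1/S list had camera adjusted p = 3.36e-21 and adjusted p = 0.466 with an estimated correlation. Of 35 mitosis genes 4 rose, 0 fell and 31 did neither (15 and 0 adjusted over the list alone), with Top2a (2.54 ± 0.51) and Cdk1 (2.39 ± 0.53). The mitosis list had camera adjusted p = 2.54e-12 and adjusted p = 0.601 with an estimated correlation. Of 14 fatty acid synthesis genes 0 rose, 7 fell and 7 did neither (0 and 9 adjusted over the list alone), with the desaturase Scd1 (-1.54 ± 0.39) and the carboxylase Acacb (-1.80 ± 0.31). The fatty acid synthesis list had camera adjusted p = 3.47e-05 and adjusted p = 0.555 with an estimated correlation. Of 22 cholesterol synthesis genes 0 rose, 7 fell and 15 did neither (0 and 9 adjusted over the list alone), with Sc5d (-1.45 ± 0.20) and Insig1 (-1.95 ± 0.42). The cholesterol synthesis list had camera adjusted p = 0.000221 and adjusted p = 0.695 with an estimated correlation. Of 20 hepatocyte factors and plasma proteins 0 rose, 11 fell and 9 did neither (0 and 11 adjusted over the list alone), including Alb (-0.73 ± 0.18) and Cebpa (-0.82 ± 0.16). The hepatocyte list had camera adjusted p = 0.00163 and adjusted p = 0.555 with an estimated correlation. Of 7 pericentral genes 2 rose, 0 fell and 5 did neither (2 and 0 adjusted over the list alone), with Oat (1.73 ± 0.15) and Lect2 (0.86 ± 0.14), and of 10 periportal genes 0 rose, 3 fell and 7 did neither (0 and 3 adjusted over the list alone), with Cyp2f2 (-1.70 ± 0.18) and Gls2 (-1.04 ± 0.23). The pericentral list had camera adjusted p = 0.0369 and adjusted p = 0.555 with an estimated correlation. The periportal list had camera adjusted p = 0.015 and adjusted p = 0.555 with an estimated correlation. Of 23 acute phase genes 4 rose, 0 fell and 19 did neither (8 and 0 adjusted over the list alone). The acute phase list had camera adjusted p = 3.47e-05 and adjusted p = 0.723 with an estimated correlation. Of 17 genes of the urea cycle and amino acid breakdown 2 rose, 4 fell and 11 did neither (2 and 4 adjusted over the list alone), with the ornithine transcarbamylase Otc (-1.10 ± 0.19) lower.

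edgeR called 386 higher and 464 lower at 24 h in 18 libraries and 154 and 203 in 16. Of these 154, 132 lay above sham replicate 2's value or bound. The 850 calls became 318 without sham replicate 1, 358 without sham replicate 2 and 465 without 24 h replicate 2. The 357 of 16 libraries became 104 without 24 h replicate 2. On log2(RPKM + 1) 691 were higher and 350 lower.

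The median of the mitosis list against sham was highest at 48 h, and most of its genes were still above sham at 72 h. How the list differed between 48 and 72 h is not reported here. In 16 libraries Cdc20, an activator of the anaphase-promoting complex, rose from 2.87 to 177 ± 2.39 CPM (log2 5.94 ± 0.86, adjusted p = 0.00121; gene 107995, chromosome 4, 118432901 to 118437343). All 35 mitosis genes measured rose (median 4.50, 35 rose and 0 fell when adjusted over the list alone), including the kinases Cdk1 (4.88 ± 0.54) and Plk1 (5.85 ± 0.69), the spindle protein Prc1 (5.91 ± 0.72) and the transcription factor Foxm1 (4.50 ± 0.56). The mitosis list had camera adjusted p = 8.47e-32 and adjusted p = 0.466 with an estimated correlation. Of 31 genes of G1/S and replication 26 rose, 0 fell and 5 did neither (28 and 0 adjusted over the list alone), with Lig1 (3.02 ± 0.37), Rrm1 (2.52 ± 0.33) and Mcm5 (3.20 ± 0.43). The G1/S list had camera adjusted p = 2.70e-18 and adjusted p = 0.466 with an estimated correlation. In 18 libraries Ccnd1 reached 247 ± 77.7 CPM (log2 2.77 ± 0.29, adjusted p = 5.16e-05), and Ube2s, a mitotic ubiquitin-conjugating enzyme, rose by 2.95 ± 0.20, adjusted p = 5.00e-06. Hmgn2 (2.42 ± 0.20), Marco (3.10 ± 0.59), Gstm3 (3.05 ± 0.71) and Steap4 (2.42 ± 0.71) were the others of the largest rises.

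Among the genes that fell at 48 h, Cyp8b1, the sterol 12-hydroxylase of bile acid synthesis, went from 359.7 ± 27.3 to 18.4 ± 8.48 CPM (log2 -4.29 ± 0.83, adjusted p = 0.00198), and the urinary protein genes Mup1, Mup11, Mup12, Mup16 and Mup17 fell, with Mup12 at -4.21 ± 0.42, adjusted p = 4.58e-05. Of 18 bile acid genes 0 rose, 13 fell and 5 did neither (0 and 13 adjusted over the list alone), with Cyp27a1 (-1.40 ± 0.20), Baat (-0.99 ± 0.15) and Slc27a5 (-1.13 ± 0.19). The bile acid list had camera adjusted p = 8.19e-05 and adjusted p = 0.555 with an estimated correlation. Every measured male-biased gene of 18 libraries fell (14 of 14, also when adjusted over the list alone; median -2.17), with Serpina12 (-3.40 ± 0.44) and Nudt7 (-1.92 ± 0.29). The male-biased list had camera adjusted p = 6.50e-08 and adjusted p = 0.555 with an estimated correlation. Of 10 female-biased genes in 16 libraries 3 rose, 0 fell and 7 did neither (3 and 0 adjusted over the list alone), with Acot3 (3.85 ± 0.90) higher. The female-biased list had camera adjusted p = 0.00844 and adjusted p = 0.572 with an estimated correlation. Their median was 2.42, or 0.87 with the 2 members at 0 sham reads set to the bound of 3 reads. Of 16 cytochrome P450 genes 1 rose, 10 fell and 5 did neither (1 and 10 adjusted over the list alone), with Cyp2c37 (-1.32 ± 0.27) and Cyp2d9 (-1.33 ± 0.17) lower. The P450 list had camera adjusted p = 0.00287 and adjusted p = 0.555 with an estimated correlation. Of 22 cholesterol synthesis genes 1 rose, 11 fell and 10 did neither (1 and 11 adjusted over the list alone), with Idi1 (-2.30 ± 0.37) and Cyp51 (-1.43 ± 0.25) lower. The cholesterol synthesis list had camera adjusted p = 0.0138 and adjusted p = 0.837 with an estimated correlation. Matrix and stellate cell genes had a median of 0.90 in 16 libraries: of 16 genes 5 rose, 2 fell and 9 did neither (7 and 2 adjusted over the list alone), with Col4a1 (1.57 ± 0.29) higher and the stellate cell gene Lrat (-2.03 ± 0.49) lower. The matrix list had camera adjusted p = 0.017 and adjusted p = 0.762 with an estimated correlation. The cell cycle inhibitors Cdkn1a (2.31 ± 0.35) and Cdkn2c (2.71 ± 0.35) were also higher, within a p53 and inhibitor list of which 4 rose, 1 fell and 10 did neither (4 and 1 adjusted over the list alone).

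edgeR called 881 genes higher and 925 lower at 48 h in 18 libraries and 935 and 885 in 16. Of these 935, 807 lay above sham replicate 2's value or bound. The 1806 calls became 932 without sham replicate 1, 1164 without sham replicate 2, 1082 without 48 h replicate 1 and 978 without 48 h replicate 2. The 1820 of 16 libraries became 906 without 48 h replicate 1 and 702 without 48 h replicate 2. Scaled by totals alone on log2(RPKM + 1), 1422 were higher and 598 lower.

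At 72 h most mitosis genes were still above sham, and some lipid synthesis genes were higher. Prc1 rose from 1.50 to 41.8 ± 13.7 CPM (log2 4.79 ± 0.71, adjusted p = 0.00457), and of 35 mitosis genes 31 rose, 0 fell and 4 did neither (35 and 0 adjusted over the list alone), with Cdk1 (3.76 ± 0.53), Top2a (3.53 ± 0.52) and Tpx2 (4.57 ± 0.70). The mitosis list had camera adjusted p = 5.20e-35 and adjusted p = 0.466 with an estimated correlation. Of 31 genes of G1/S and replication 12 rose, 0 fell and 19 did neither (27 and 0 adjusted over the list alone). The G1/S list had camera adjusted p = 1.97e-18 and adjusted p = 0.466 with an estimated correlation. Ccnd1 stood at 232 ± 100 CPM (log2 2.68 ± 0.28, adjusted p = 0.000244), and Lpl, lipoprotein lipase, rose from 31.9 ± 10.1 to 162 ± 51.0 CPM (log2 2.35 ± 0.32, adjusted p = 0.000864). Gstm3 (3.45 ± 0.72), Gstm2 (2.09 ± 0.28) and Marco (2.40 ± 0.58) were also higher. Mup17 fell from 816 ± 61.5 to 14.2 ± 1.83 CPM (log2 -5.84 ± 0.85, adjusted p = 0.00101), and Mup1, Mup7, Mup11, Mup16 and Mup21 were the other genes of the largest falls.

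Of 14 fatty acid synthesis genes 7 rose, 1 fell and 6 did neither (11 and 1 adjusted over the list alone), with citrate lyase Acly (1.67 ± 0.36) and the carboxylase Acaca (1.23 ± 0.22) higher. The fatty acid synthesis list had camera adjusted p = 0.000215 and adjusted p = 0.555 with an estimated correlation. Of 22 cholesterol synthesis genes 4 rose, 0 fell and 18 did neither (8 and 0 adjusted over the list alone), with Lss (1.41 ± 0.19) and Pmvk (1.22 ± 0.22). The cholesterol synthesis list had camera adjusted p = 0.00245 and adjusted p = 0.78 with an estimated correlation. Of 16 matrix and stellate cell genes 8 rose, 0 fell and 8 did neither (10 and 1 adjusted over the list alone), with the fibrillar collagens Col1a1 (3.32 ± 0.60) and Col3a1 (2.44 ± 0.42). The matrix list had camera adjusted p = 1.19e-07 and adjusted p = 0.466 with an estimated correlation. Of 14 male-biased genes 0 rose, 12 fell and 2 did neither (0 and 14 adjusted over the list alone). The male-biased list had camera adjusted p = 4.28e-10 and adjusted p = 0.555 with an estimated correlation. Of 16 cytochrome P450 genes 0 rose, 11 fell and 5 did neither (0 and 11 adjusted over the list alone). Of 18 bile acid genes 0 rose, 7 fell and 11 did neither (0 and 8 adjusted over the list alone), with the uptake transporter gene Slco1a1 (-2.45 ± 0.54) and Cyp7b1 (-2.45 ± 0.55). The P450 list had camera adjusted p = 8.19e-05 and adjusted p = 0.555 with an estimated correlation. The bile acid list had camera adjusted p = 0.00018 and adjusted p = 0.555 with an estimated correlation. Afp, the fetal plasma protein, rose by 2.38 ± 0.55, the 1 call among 4 oncofetal genes (2 and 0 when adjusted over the list alone). The oncofetal list had camera adjusted p = 0.0208 and adjusted p = 0.466 with an estimated correlation. Cholangiocyte and progenitor markers, 8 genes, had a median of 0.81 with 0 past the test by gene (3 rose and 0 fell when adjusted over the list alone). The cholangiocyte list had camera adjusted p = 0.0187 and adjusted p = 0.664 with an estimated correlation.

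edgeR called 302 higher and 315 lower at 72 h in 18 libraries and 309 and 157 in 16. Of these 309, 243 lay above sham replicate 2's value or bound. The 617 calls became 186 without sham replicate 1, 234 without sham replicate 2 and 108 without 72 h replicate 2. The 466 of 16 libraries became 48 without 72 h replicate 2. On log2(RPKM + 1) 524 were higher and 225 lower.

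At 120 h the genes called against sham included single matrix and macrophage genes, which were higher, and urinary protein genes, which were lower. Sparc, a collagen-binding matrix protein, rose from 80.98 ± 10.9 to 234 ± 37.1 CPM (log2 1.53 ± 0.19, adjusted p = 0.00224), and Cd5l, a protein secreted by macrophages, from 128 ± 8.07 to 343 ± 45.9 CPM (log2 1.42 ± 0.23, adjusted p = 0.0169). Marco (2.78 ± 0.59), Lpl (1.74 ± 0.32), Pkm (1.55 ± 0.32) and Ccnd1 (1.44 ± 0.28) were higher too. Gdf15 fell from 22.8 ± 2.42 to 3.27 ± 0.246 CPM (log2 -2.80 ± 0.31, adjusted p = 0.0011), and Mup16 (-4.23 ± 0.45), Mup21 (-4.03 ± 0.57), Mup11, Mup12 and Mup17 fell. Of 10 Kupffer cell and macrophage markers 2 rose, 0 fell and 8 did neither (7 and 0 adjusted over the list alone). The macrophage list had camera adjusted p = 3.05e-06 and adjusted p = 0.555 with an estimated correlation. Of 14 male-biased genes 0 rose, 0 fell and 14 did neither (0 and 12 adjusted over the list alone). Of 8 NRF2 antioxidant targets 0 rose, 0 fell and 8 did neither (6 and 0 adjusted over the list alone). The male-biased list had camera adjusted p = 3.30e-08 and adjusted p = 0.555 with an estimated correlation. The NRF2 list had camera adjusted p = 0.00111 and adjusted p = 0.555 with an estimated correlation. Matrix and stellate cell genes, 16 in 16 libraries, had a median of 1.29: 0 rose, 0 fell and 16 did neither (8 and 0 adjusted over the list alone), with Col4a2 (1.34 ± 0.27) at adjusted p = 0.123. The matrix list had camera adjusted p = 5.25e-06 and adjusted p = 0.495 with an estimated correlation. Mitosis genes had a median of 1.41 with 0 of 35 past the test by gene. The mitosis list had camera adjusted p = 1.12e-09 and adjusted p = 0.621 with an estimated correlation. Of 10 immediate early genes 0 rose, 3 fell and 7 did neither (0 and 4 adjusted over the list alone), with Egr1 (-2.74 ± 0.46) and Ier2 (-1.62 ± 0.30) lower. The immediate early list had camera adjusted p = 0.000519 and adjusted p = 0.555 with an estimated correlation.

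edgeR called 19 genes higher and 19 lower at 120 h in 18 libraries and 3 and 10 in 16; all 3 lay above sham replicate 2's value or bound. The balance of the 16-library calls turned over with DESeq2, at 45 higher and 29 lower, and without a filter on low counts, at 210 and 120; in 18 libraries DESeq2 gave 115 and 83. The 38 calls became 5 without sham replicate 1, 4 without sham replicate 2, 84 and 89 without 24 h replicate 1 or 2, 15 and 6 without 120 h replicate 1 or 2 and 24 without 168 h replicate 1. The 13 calls of 16 libraries became 23 without either 24 h library, 8 without either 48 h library or either 168 h library and 1 without 120 h replicate 2.

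At 168 h, the last time sampled, genes of MHC class II were among the largest rises called. Cd74, the invariant chain of MHC class II, rose from 76.7 ± 12.3 to 431 ± 134 CPM (log2 2.49 ± 0.41, adjusted p = 0.0151), and the class II chains H2-Eb1 (3.09 ± 0.37), H2-Aa (2.61 ± 0.44) and H2-Ab1 (2.50 ± 0.55) rose. In replicates 1 and 2 of 168 h Cd74 was at 336 and 526 CPM, H2-Eb1 at 80.4 and 136 CPM, H2-Aa at 94.8 and 146 CPM and H2-Ab1 at 83.9 and 134 CPM. The replicate 2 pool also stood above replicate 1 in 15 of 15 interferon-inducible genes, a set picked after its values were seen, by a median of 1.57. Marco was at 181 ± 11.1 CPM (log2 3.29 ± 0.60, adjusted p = 0.0183), and Cd44 (1.86 ± 0.40), a hyaluronan receptor, was higher. Mup21 fell from 511 ± 50.0 to 16.2 ± 2.53 CPM (log2 -4.98 ± 0.60, adjusted p = 0.00122), and Mup7, Mup11, Mup12, Mup16 and Mup17 were the other genes of the largest falls. Of 10 Kupffer cell and macrophage markers 7 rose, 0 fell and 3 did neither (9 and 0 adjusted over the list alone), with the complement genes C1qb (1.20 ± 0.24) and C1qc (1.14 ± 0.25) and with Cd5l (1.59 ± 0.23). The macrophage list had camera adjusted p = 6.50e-08 and adjusted p = 0.555 with an estimated correlation. Of 14 male-biased genes 0 rose, 3 fell and 11 did neither (0 and 7 adjusted over the list alone), with Mup20 (-2.59 ± 0.45) and C8a (-0.78 ± 0.16). The male-biased list had camera adjusted p = 2.06e-05 and adjusted p = 0.555 with an estimated correlation. Of 20 hepatocyte factors and plasma proteins 1 rose, 2 fell and 17 did neither (2 and 2 adjusted over the list alone), with Ttr (0.56 ± 0.15) higher and F9 (-0.84 ± 0.21) lower. Mitosis genes in 16 libraries had a median of 1.03 with 0 of 35 past the test by gene. The mitosis list had camera adjusted p = 3.57e-05 and adjusted p = 0.774 with an estimated correlation.

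edgeR called 118 genes higher and 164 lower at 168 h in 18 libraries and 3 and 7 in 16; 2 of the 3 lay above sham replicate 2's value or bound, and with RLE factors the 16-library counts were 1 and 7. With limma-trend on log2 CPM the balance in 16 libraries turned over to 20 higher and 12 lower, and with edgeR in 18 libraries it did so without 168 h replicate 1, at 35 and 15. The 282 calls became 8 without sham replicate 1, 5 without sham replicate 2, 634 and 665 without 24 h replicate 1 or 2, 159 and 170 without 48 h replicate 1 or 2, and 50 and 7 without 168 h replicate 1 or 2. The 10 calls of 16 libraries became 6 without either 2 h library, 237 and 238 without 24 h replicate 1 or 2, 25 without either 120 h library and 0 without either 168 h library.

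**Figure D2:**
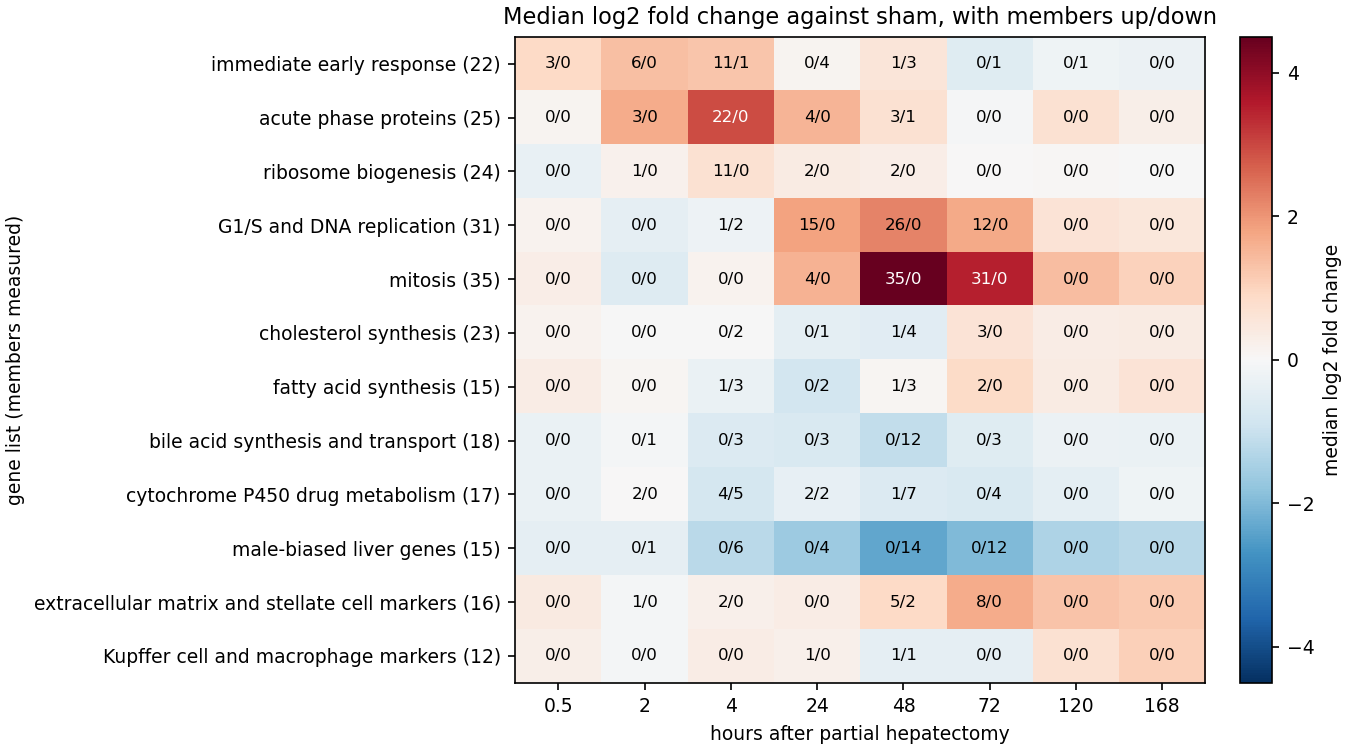
Median log2 fold change against sham of 12 gene lists (down the side) at 8 times (along the bottom) in the 16-library test, with the members called higher and lower written in each cell. Acute phase genes peaked at 4 h with a median of 2.92, and mitosis genes at 48 h with a median of 4.50.

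Successive times were compared without sham. From 0.5 to 2 h, Steap4 rose from 298 ± 122 to 2280.3 ± 822 CPM (log2 2.93 ± 0.73, adjusted p = 0.0177), and Gpcpd1 (2.90 ± 0.32) and B3galt1 (2.66 ± 0.50) rose as well. Hhex (-4.26 ± 0.43), Nr0b2 (-3.24 ± 0.64) and Arrdc3 (-3.04 ± 0.32) fell. In 16 libraries Socs3, a feedback inhibitor of cytokine signalling, rose by 4.05 ± 0.89, adjusted p = 0.0278, and of 8 erythroid genes 0 rose, 4 fell and 4 did neither (0 and 5 adjusted over the list alone). edgeR called 327 higher and 326 lower in 18 libraries and 199 and 192 in 16. The 653 calls became 354 without 0.5 h replicate 2, 282 without 2 h replicate 1 and 402 without 2 h replicate 2, the 391 of 16 libraries became 181 and 180 without 2 h replicate 1 or 2, and on log2(RPKM + 1) 173 were higher and 878 lower.

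Between 2 and 4 h, Hhex returned from 5.12 ± 1.42 to 42.7 ± 26.1 CPM (log2 3.06 ± 0.43, adjusted p = 0.000805), and Apcs, the serum amyloid P component, rose from 625 ± 211 to 3168 ± 296 CPM (log2 2.34 ± 0.52, adjusted p = 0.0111). Marco rose by 2.35 ± 0.59, while Hsd3b5 (-2.85 ± 0.57), Mcm10 (-2.47 ± 0.54) and Sdr9c7 (-2.34 ± 0.42) fell. Of 25 acute phase genes in 16 libraries 8 rose, 0 fell and 17 did neither (18 and 0 adjusted over the list alone). Of 24 ribosome biogenesis genes 6 rose, 0 fell and 18 did neither (13 and 0 adjusted over the list alone). Of 17 cytochrome P450 genes 0 rose, 6 fell and 11 did neither (1 and 8 adjusted over the list alone). edgeR called 276 higher and 443 lower in 18 libraries and 318 and 499 in 16. The 719 calls became 247 without 2 h replicate 2, 225 without 4 h replicate 1 and 414 without 4 h replicate 2. The 817 of 16 libraries became 460 and 169 without 2 h replicate 1 or 2 and 197 and 380 without 4 h replicate 1 or 2. Scaled by totals alone on log2(RPKM + 1), 113 were higher and 1185 lower.

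From 4 to 24 h most immediate early genes came down and most replication genes came up. Arhgef19, a guanine nucleotide exchange factor, rose from 7.27 ± 0.213 to 64.5 ± 1.30 CPM (log2 3.15 ± 0.14, adjusted p = 1.79e-08), and Apol7a (2.93 ± 0.20) and Ppp1r3c, a glycogen-targeting phosphatase subunit (2.86 ± 0.28), rose. B3galt1 (-4.10 ± 0.52), Upp2 (-4.01 ± 0.36) and Tifa (-3.86 ± 0.82) fell, as did Tiparp (-4.75 ± 0.35) in 16 libraries. Of 31 genes of G1/S and replication 28 rose, 0 fell and 3 did neither (30 and 0 adjusted over the list alone). Of 22 immediate early genes 0 rose, 16 fell and 6 did neither (0 and 16 adjusted over the list alone). Of 25 acute phase genes 0 rose, 13 fell and 12 did neither (0 and 17 adjusted over the list alone). Of 11 pericentral genes 7 rose, 0 fell and 4 did neither (7 and 0 adjusted over the list alone). Of 16 clock genes 8 rose, 1 fell and 7 did neither (8 and 1 adjusted over the list alone). edgeR called 859 higher and 834 lower in 18 libraries and 1422 and 1308 in 16, which became 1653 and 1702 in all without 4 h replicate 1 or 2. On log2(RPKM + 1) 2716 were higher and 263 lower.

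From 24 to 48 h the mitotic list rose: of 35 genes 34 rose, 0 fell and 1 did neither (35 and 0 adjusted over the list alone), with cyclin B2, Ccnb2, going from 2.17 ± 0.71 to 69.8 ± 11.9 CPM (log2 4.996 ± 0.54, adjusted p = 0.000374). Inmt, a methyltransferase, rose by 2.75 ± 0.25, adjusted p = 8.80e-05, and Egr1 (2.59 ± 0.46) and the chemokine Ccl9 (2.41 ± 0.24) rose. Apcs (-2.35 ± 0.52), Mup12 (-1.90 ± 0.46) and Idi1 (-1.81 ± 0.37) fell, and of 15 fatty acid synthesis genes 7 rose, 0 fell and 8 did neither (10 and 0 adjusted over the list alone). edgeR called 386 higher and 323 lower in 18 libraries and 512 and 290 in 16. Scaled by totals alone on log2(RPKM + 1), 483 were higher and 221 lower. The 709 calls became 131 and 1085 without 24 h replicate 1 or 2 and 154 and 179 without 48 h replicate 1 or 2. The 802 of 16 libraries became 221 and 1222 without 24 h replicate 1 or 2 and 235 and 222 without 48 h replicate 1 or 2.

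Some lipid synthesis genes rose from 48 to 72 h. Scd1, the stearoyl-CoA desaturase, went from 3118 ± 1016 to 13114 ± 2313 CPM (log2 2.07 ± 0.39, adjusted p = 0.0137), Acss2, an acetyl-CoA synthetase, rose by 2.17 ± 0.39, adjusted p = 0.0107, and Idi1 rose by 2.05 ± 0.37, adjusted p = 0.0107. Of 23 cholesterol synthesis genes 8 rose, 0 fell and 15 did neither (17 and 0 adjusted over the list alone). Of 15 fatty acid synthesis genes 5 rose, 0 fell and 10 did neither (10 and 0 adjusted over the list alone). Saa3 (-5.57 ± 1.29), Mbd1 (-1.61 ± 0.27) and Ube2s (-1.31 ± 0.18) fell. edgeR called 110 higher and 70 lower in 18 libraries and 52 and 28 in 16. On log2(RPKM + 1) 81 were higher and 129 lower. The 180 calls became 118 and 117 without sham replicate 1 or 2, 113 without 0.5 h replicate 1, 64 and 0 without 48 h replicate 1 or 2, 6 without 72 h replicate 1 and 95 and 97 without 168 h replicate 1 or 2. The 80 of 16 libraries became 32 and 0 without 48 h replicate 1 or 2, 10 without 72 h replicate 1 and 37 without either 168 h library.

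From 72 to 120 h most mitosis genes fell: of 35 in 16 libraries 0 rose, 22 fell and 13 did neither (0 and 35 adjusted over the list alone), with Cdc20 going from 66.8 ± 27.5 to 12.1 ± 11.8 CPM (log2 -2.47 ± 0.52, adjusted p = 0.0394). Irf7, an interferon regulatory factor, rose from 21.2 ± 0.424 to 133 ± 63.5 CPM (log2 2.65 ± 0.42, adjusted p = 0.0138), with H2-Aa (2.37 ± 0.47) and Cd74 (2.27 ± 0.41). The 120 h pools stood apart in these genes: in replicates 1 and 2 Irf7 was at 88.3 and 178 CPM, H2-Aa at 24.5 and 68.0 CPM and Cd74 at 92.7 and 233 CPM. Of 12 Kupffer cell and macrophage markers 6 rose, 0 fell and 6 did neither (10 and 0 adjusted over the list alone). Ccnd1 (-1.24 ± 0.27), Apoc2 (-1.16 ± 0.17) and Lss (-1.16 ± 0.19) fell. edgeR called 40 higher and 17 lower in 18 libraries and 48 and 88 in 16. Scaled by totals alone on log2(RPKM + 1), 36 were higher and 42 lower. The 57 calls became 130 and 0 without 72 h replicate 1 or 2 and 0 without 120 h replicate 2. The 136 of 16 libraries became 79 and 76 without 2 h replicate 1 or 2, 89 without either 4 h library, 5 without either 48 h library, 282 and 0 without 72 h replicate 1 or 2 and 0 without 120 h replicate 2.

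From 120 to 168 h edgeR called 0 genes in either test, with 163 of 4906 and 367 of 12199 at an unadjusted p under 0.05; DESeq2 called 1 gene in each, limma-trend on log2 CPM 0 in each, and the 18-library count was 1 without 120 h replicate 2.

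The direct comparison of 168 h with 48 h asked how far the 48 h profile had receded. Cyp8b1 rose from 18.4 ± 8.48 to 355 ± 20.5 CPM (log2 4.27 ± 0.83, adjusted p = 0.00333), next to a sham level of 359.7 ± 27.3 CPM, and the class II genes H2-Eb1 (4.05 ± 0.39) and H2-Ab1 (3.90 ± 0.59) rose, more in replicate 2 of 168 h than in replicate 1. The acute phase genes Saa3 (-5.02 ± 1.24), Mt2 (-3.63 ± 1.07) and Mt1 (-3.20 ± 1.02) fell. All 35 mitosis genes fell in 16 libraries, 35 also when adjusted over the list alone, and of 31 genes of G1/S and replication 0 rose, 28 fell and 3 did neither (0 and 29 adjusted over the list alone). Of 23 cholesterol synthesis genes 12 rose, 0 fell and 11 did neither (16 and 0 adjusted over the list alone). Of 18 bile acid genes 7 rose, 0 fell and 11 did neither (9 and 0 adjusted over the list alone). Of 21 hepatocyte factors and plasma proteins 7 rose, 0 fell and 14 did neither (7 and 0 adjusted over the list alone). Of 12 macrophage markers 10 rose, 0 fell and 2 did neither (11 and 0 adjusted over the list alone). edgeR called 562 higher and 457 lower in 18 libraries and 847 and 836 in 16. The 16-library balance was not firm: 408 higher and 497 lower had an estimated change of at least 2-fold. Lower calls also outnumbered higher ones there without either 48 h library and without 168 h replicate 2. On log2(RPKM + 1) 367 were higher and 940 lower. The 1019 calls became 563 and 371 without 48 h replicate 1 or 2 and 544 and 432 without 168 h replicate 1 or 2. The 1683 of 16 libraries became 784 and 535 without 48 h replicate 1 or 2 and 946 and 446 without 168 h replicate 1 or 2.

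**Figure D3:**
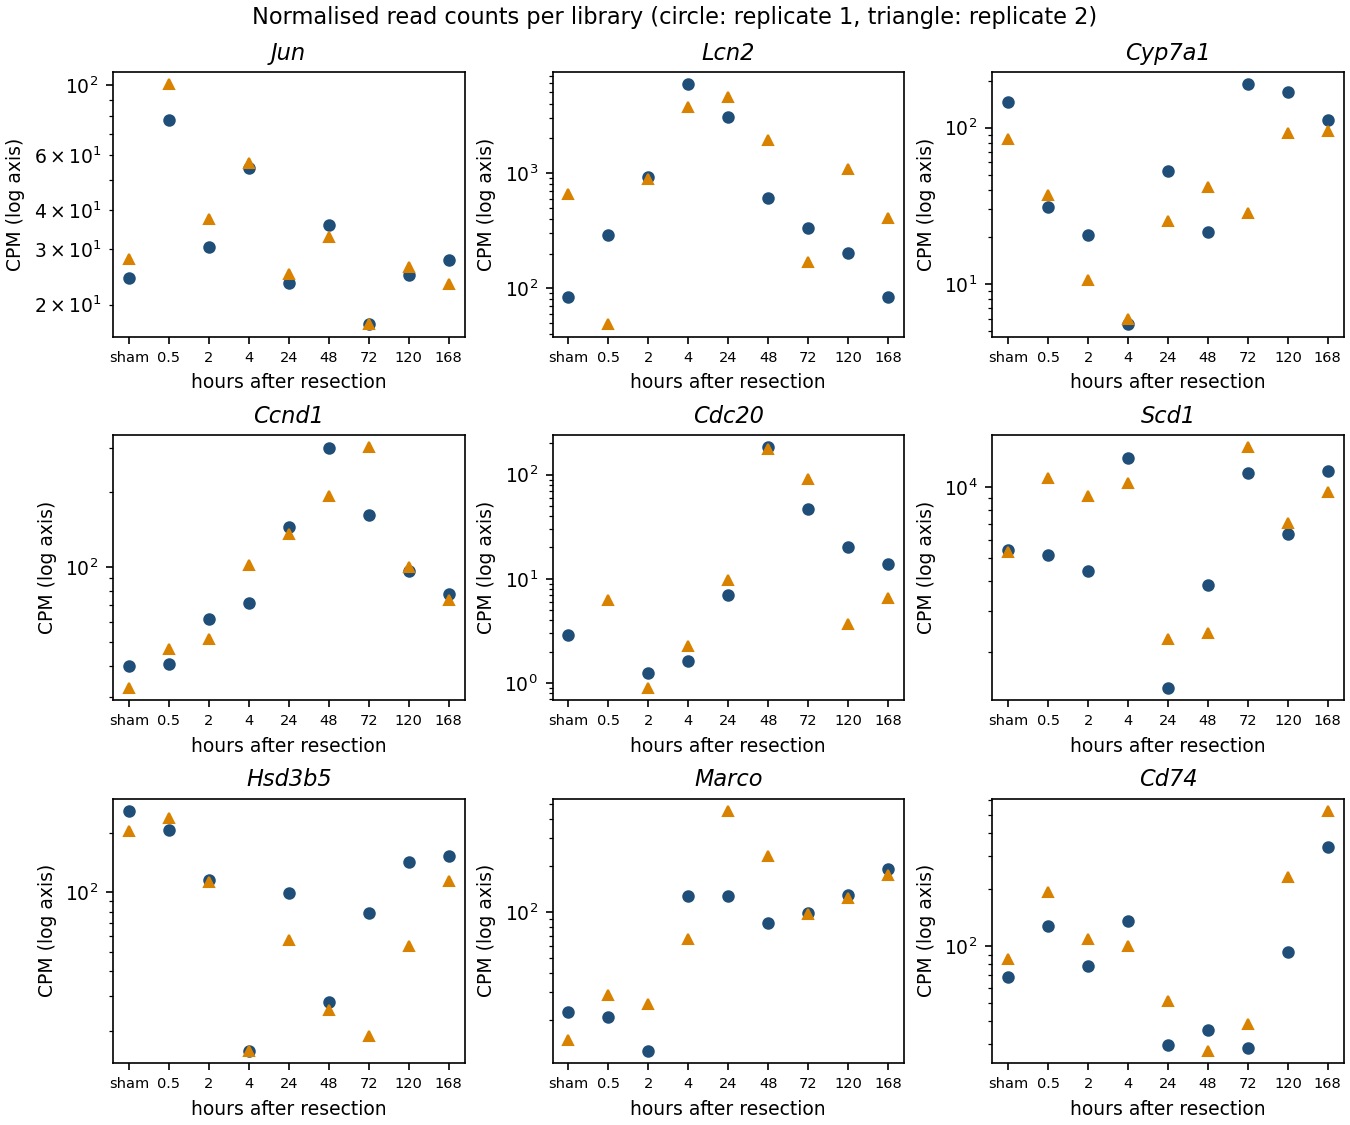
Levels of 9 named genes in CPM on a log axis against group, with circles for replicate 1 and triangles for replicate 2 of each group; a gene that a short table does not list has no point there. Jun was at 89.0 ± 16.6 CPM at 0.5 h, and Cd74 at 431 ± 134 CPM at 168 h.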

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

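The comparisons of 2 times in this part were chosen after the list calls against sham had been seen to go in opposite directions, as were the tests of the male-biased genes and the tests of lipid synthesis by totals and by single libraries, whereas the test of the time of day was written before its result was seen.

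The list of immediate early genes stood above sham at 0.5 h and below at 120 h in 18 libraries. Compared directly, they were higher at 0.5 h by a median of 1.90 (camera adjusted p = 3.11e-21, adjusted p = 0.00281 with an estimated correlation), and 7 of 10 members passed the direct test. Mitosis genes in the 16 libraries were below sham at 2 h by a median of -0.57 (camera adjusted p = 0.00383, adjusted p = 0.777 with an estimated correlation) and above at 72 h, with a direct difference of 4.33 (camera adjusted p = 3.21e-31, adjusted p = 0.0343 with an estimated correlation; 35 of 35 members higher). Ribosome biogenesis genes were higher at 4 h than at 0.5 h by 1.07 (camera adjusted p = 1.89e-10, adjusted p = 0.00558 with an estimated correlation; 17 of 24 members). The list calls against sham that these comparisons start from rest on camera's preset correlation. With an estimated one the lowest adjusted p of any list against sham were 0.555 in 18 libraries and 0.466 in 16. For each list, here and for lipid synthesis below, the 2 times were those with the smallest p above and below sham. The direction of the direct difference was therefore set by that choice, and its p-values are no independent support. They were adjusted over these direct comparisons alone, so they cannot be set beside those adjusted over 208 and 272 list tests.

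Cholesterol synthesis genes were higher at 72 h than at 24 h by 1.05 in 18 libraries (camera adjusted p = 2.64e-13, adjusted p = 0.0403 with an estimated correlation; 11 of 22 members) and by 0.96 in 16 (camera adjusted p = 1.78e-16, adjusted p = 0.0403 with an estimated correlation; 11 of 23). Fatty acid synthesis genes were higher at 72 h by 1.60 in 18 libraries (camera adjusted p = 2.02e-16, adjusted p = 0.00944 with an estimated correlation; 12 of 14) and by 1.66 in 16 (camera adjusted p = 8.53e-24, adjusted p = 0.00558 with an estimated correlation; 13 of 15).

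That swing in lipid synthesis was weighed against technical explanations. The tests by totals and by single libraries replaced earlier ones, after the values of those had been seen, because TMM scaling and the choice of members past the test had set their outcome. With libraries scaled by their totals alone, the median of all 4906 genes moved by -0.0371 from 24 to 72 h and those of the cholesterol and fatty acid lists by 1.04 and 1.59, which argues against a few abundant genes taking another share of the counts. Between single libraries, the lowest median of a 72 h library over a 24 h library was 0.723 for the cholesterol list and 1.37 for the fatty acid list, next to medians of at most 0.370 and 0.194 between replicates. That argues against 1 library standing apart as the whole of it; of the 36 members measured, 31 had both 72 h libraries above both 24 h libraries. Collection at another time of day stays open. Of the clock genes, Per3 differed by 1.41 ± 0.48 (adjusted p = 0.126), so its range of 2 SE reached 2.38, the farthest from 0 of the 4 compared. Dbp differed by 0.91 ± 0.55 (adjusted p = 0.424), Nr1d1 by 0.36 ± 0.39 (adjusted p = 0.685) and Arntl by 0.31 ± 0.14 (adjusted p = 0.264). Another time of day was expected to move Arntl against the other 3, which these values do not show, but with ranges this wide they do not exclude it. A response to feeding or to lipid demand of the regrowing liver could also account for it and was not tested.

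Male-biased genes of the liver fell at 48 h, with a median of -2.34 over 15 members in the 16 libraries. RNA of female mice is argued against by Xist, with 0 of 17861110 reads in the 48 h libraries, which allows 0.168 CPM, although the 4 Y-linked genes were lower: Eif2s3y by -1.52 ± 0.28 (adjusted p = 0.0044), Ddx3y by -1.21 ± 0.45 (adjusted p = 0.0851), Kdm5d by -0.96 ± 0.38 (adjusted p = 0.104) and Uty by -0.78 ± 0.37 (adjusted p = 0.165). The 4 were low at 168 h too, where both libraries lay below both sham libraries for each of them. Ddx3y was at 13.1 and 11.3 CPM there, next to 33.4 and 35.97 CPM in sham. Uty was at 4.38 and 3.73 CPM, next to 10.3 and 9.399 CPM in sham. At 4 h, in contrast, Ddx3y and Uty lay above both sham libraries. The low levels were therefore not particular to the 48 h pools, and what lowered these genes is open. Shared reads of the Mup copies are argued against by the 14 members outside that family, with a median of -2.29 (SD 0.834). A lower share of hepatocytes is argued against by the hepatocyte list, with a median of -0.22 over 21 members. A loss of the growth hormone pattern that sets male expression may be involved, which was not tested.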

How the results depend on the processing

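The tests of the 16 complete libraries, with their alternatives, and of the genes listed in every file were chosen only after the tables had been seen to end early, and every other setting below was chosen before the data were examined.

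With DESeq2 in 18 libraries the counts against sham became 127 at 0.5 h, 966 at 72 h, 198 at 120 h and 854 at 168 h. Among resected groups they became 1080 from 24 to 48 h, 485 from 48 to 72 h, 290 from 72 to 120 h and 1 from 120 to 168 h. With DESeq2 in the 16 complete libraries the counts against sham became 20 at 0.5 h, 74 at 120 h and 259 at 168 h. Among resected groups they became 225 from 48 to 72 h, 306 from 72 to 120 h and 1 from 120 to 168 h. DESeq2 gave more calls than edgeR's quasi-likelihood test at these points. The simulated comparisons did not include these points and gave every gene a dispersion of 0.02, so they cannot tell whether the extra calls are false. With 200 changed genes among 4906, DESeq2 gave 19 false calls of 209 at 48 h against sham, where edgeR gave 7 of 199. From 2 to 4 h it gave 12 of 205 against 6 of 197. Over 12199 genes the false calls lay close together, at 6 of 113 for DESeq2 against 5 of 124 at 48 h and 11 of 159 against 10 of 170 from 2 to 4 h.

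Calls were also limited to estimated changes of at least 2-fold, without a test against that change. In 18 libraries the counts against sham then became 167 at 2 h, 511 at 4 h and 173 at 24 h. At later times they became 357 at 48 h, 144 at 72 h and 83 at 168 h. For pairs of resected groups they became 159 from 0.5 to 2 h, 142 from 2 to 4 h, 470 from 4 to 24 h, 103 from 24 to 48 h, 41 from 48 to 72 h, 23 from 72 to 120 h and 202 from 48 to 168 h. In the 16 complete libraries this test gave against sham 1177 at 48 h. For pairs of resected groups they became 389 from 2 to 4 h, 1453 from 4 to 24 h, 405 from 24 to 48 h, 48 from 48 to 72 h and 905 from 48 to 168 h.

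In the 16 complete libraries over all 12199 genes the counts against sham became 6 at 0.5 h, 357 at 24 h, 13 at 120 h and 10 at 168 h. Among the other comparisons they became 391 from 0.5 to 2 h, 2730 from 4 to 24 h, 80 from 48 to 72 h, 136 from 72 to 120 h, 1683 from 48 to 168 h and 5220 among the 9 groups. In the same libraries, over the genes listed in every file the counts against sham became 4 at 0.5 h, 195 at 2 h, 1150 at 4 h, 348 at 24 h, 1138 at 48 h, 210 at 72 h, 3 at 120 h and 4 at 168 h. Among the other comparisons they became 251 from 0.5 to 2 h, 98 from 48 to 72 h and 22 from 72 to 120 h.

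When a gene that a short table did not list was taken as 0 the counts against sham became 3 at 0.5 h, 207 at 2 h, 1116 at 4 h, 423 at 24 h, 1090 at 48 h, 279 at 72 h, 2 at 120 h and 5 at 168 h. Between times after resection they became 291 from 0.5 to 2 h, 351 from 2 to 4 h, 1040 from 4 to 24 h, 277 from 24 to 48 h, 48 from 48 to 72 h, 13 from 72 to 120 h and 552 from 48 to 168 h. When only the 2 groups compared were fitted the counts against sham became 5 at 0.5 h, 354 at 24 h and 1021 at 168 h. Between times after resection they became 330 from 0.5 to 2 h, 290 from 2 to 4 h, 798 from 4 to 24 h, 28 from 24 to 48 h, 82 from 48 to 72 h and 0 from 72 to 120 h.

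Without a filter on low counts, in the 16 libraries, the counts against sham became 50 at 0.5 h, 650 at 2 h, 835 at 24 h, 914 at 72 h, 330 at 120 h and 893 at 168 h. Among resected groups they became 722 from 0.5 to 2 h, 1245 from 2 to 4 h, 1329 from 24 to 48 h, 494 from 48 to 72 h, 650 from 72 to 120 h and 9 from 120 to 168 h. With limma-trend on log2 CPM in the 16 libraries the counts against sham became 32 at 168 h. Among resected groups they became 79 from 72 to 120 h. With limma-trend on log2(RPKM + 1), scaled by totals alone, the counts against sham became 2638 at 4 h. Among resected groups they became 1051 from 0.5 to 2 h, 1298 from 2 to 4 h and 2979 from 4 to 24 h.

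Leaving out 1 library at a time in the 18-library test gave, against sham, 3 to 13 at 0.5 h, 174 to 622 at 2 h, 1116 to 2537 at 4 h, 318 to 937 at 24 h, 932 to 2497 at 48 h, 108 to 771 at 72 h, 4 to 89 at 120 h and 5 to 665 at 168 h. For resected groups it gave 282 to 765 from 0.5 to 2 h, 225 to 960 from 2 to 4 h, 1196 to 2422 from 4 to 24 h, 131 to 1085 from 24 to 48 h, 0 to 220 from 48 to 72 h, 0 to 130 from 72 to 120 h, 0 to 1 from 120 to 168 h and 371 to 1288 from 48 to 168 h. The genes that differed among the 9 groups numbered 2857 to 4677, and the list calls 47 to 68.

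Leaving out 1 library at a time in the 16-library test gave, against sham, 5 to 7 at 0.5 h, 126 to 379 at 2 h, 1125 to 2062 at 4 h, 104 to 468 at 24 h, 702 to 2227 at 48 h, 48 to 609 at 72 h, 1 to 23 at 120 h and 0 to 238 at 168 h. For resected groups it gave 180 to 516 from 0.5 to 2 h, 169 to 1005 from 2 to 4 h, 1653 to 2775 from 4 to 24 h, 221 to 1222 from 24 to 48 h, 0 to 104 from 48 to 72 h, 0 to 282 from 72 to 120 h, 0 to 0 from 120 to 168 h and 446 to 1869 from 48 to 168 h. The genes that differed among the 9 groups numbered 4095 to 5867, and the list calls 90 to 104.

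The balance of higher and lower calls turned over at further points, of which the following are examples. At 72 h against sham DESeq2 gave 503 higher and 463 lower in 18 libraries. From 4 to 24 h in 18 libraries, calls with an estimated change of at least 2-fold numbered 223 and 247. The balance also turned over from 4 to 24 h in 16 libraries without 24 h replicate 1, and at 48 h in 18 libraries without 48 h replicate 2. From 24 to 48 h without 24 h replicate 2 it became 507 higher and 578 lower in 18 libraries and 559 and 663 in 16. In the 16 libraries it became 200 and 189 from 2 to 4 h for calls with an estimated change of at least 2-fold. Without a filter on low counts it became 330 and 320 there from 72 to 120 h.

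A group left with 1 library was assumed to vary like the other groups. Without 0.5 h replicate 1 more genes were testable, because its table was the shorter of the 2 that end early, so that higher counts there follow from the construction.

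The lists called by camera with its preset correlation of 0.01 numbered 54 in 18 libraries and 95 in the 16 complete libraries, and 0 and 0 with a correlation estimated from the data, where the lowest adjusted p were 0.555 and 0.466. The rotation test fry called 45 and 19. The p53 and CDK inhibitor list at 120 h was called in 18 libraries with adjusted p = 0.0189 and turned direction in the 16, with adjusted p = 0.733. Of 862 results for named genes, 477 passed to the other side of the threshold in some alternative and 0 reversed.

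Libraries of the groups carry the same replicate numbers, and a fit with the replicate number as a replicate block moved 1 of 34 counts of calls by more than 1.5 times, to 8 calls at 120 h in the 16 libraries. Under the block 38 of 862 results for named genes and 11 of 149 list calls no longer passed the threshold, and the others kept their side of it. Deviations from the group means correlated between -0.546 and 0.530 (median 0.0432) over 36 pairs of groups in 18 libraries, with 14 over 0.1 and 9 under -0.1, and between -0.359 and 0.288 (median 0.0213) over 21 pairs in the 16, so the numbers do not pair the libraries throughout. Among sham, 24, 48, 120 and 168 h, a set picked after the correlations had been seen, the 10 pairs lay between 0.103 and 0.530, whereas 4 h ran against 24 h at -0.546 and against 120 h at -0.291. An effect shared by the same-numbered libraries of some groups therefore stays open.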

Other observations

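The gene sets of the Gene Ontology and the interferon genes in this part were chosen after their values had been seen, and so were the tests of the interferon pattern.

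Terms of the Gene Ontology with 10 to 200 measured genes were tested beside the fixed lists. At 72 h the 23 genes of extracellular matrix organization had a median of 0.73 in the 16 libraries, and 8 rose and 0 fell (camera adjusted p = 0.000573, adjusted p = 0.994 with an estimated correlation). At 120 h their median was 0.42 (camera adjusted p = 0.00183, adjusted p = 0.994 with an estimated correlation) and at 168 h 0.48 (camera adjusted p = 0.0344, adjusted p = 0.994 with an estimated correlation), and at both times 0 rose and 0 fell by edgeR's test. At 24 h, 13 of the 104 genes of S phase rose and 0 fell (camera adjusted p = 8.23e-12, adjusted p = 0.994 with an estimated correlation), and 0 rose and 7 fell among the 49 genes of steroid biosynthesis. Complement activation, with 12 genes, had a median of -0.59 at 24 h, where 0 rose and 3 fell (camera adjusted p = 0.00537, adjusted p = 0.994 with an estimated correlation).

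Interferon-inducible genes, 15 in number and among them the GTPase Igtp and the chemokine Cxcl9, were higher in replicate 2 than in replicate 1 at 120 h and at 168 h, by medians of 1.50 and 1.57, in 15 of 15 genes each time. Igtp was at 58.9 and 429 CPM in the 120 h pools and at 81.9 and 385 CPM in the 168 h pools. A batch that acts alike on every replicate 2 library is argued against by 72 h, where the median was -0.15 and 3 of the 15 genes were higher, and by 2 and 4 h, with medians of 0.10 and 0.05 and 9 of 15 genes each. The test first used the highest of the other medians, 0.86 at 24 h, and was rewritten to the lowest after that value had been seen. At 24 h 13 of 15 and at 48 h 14 of 15 genes were higher in replicate 2, by medians of 0.86 and 0.29, so that an effect shared by some replicate 2 libraries stays open. A rise of lymphocytes as large as that of these genes is argued against by 11 markers. Their summed reads had ratios of 1.14 and 1.08 with an upper 95% limit of at most 1.70, below the fold of 2.83. A smaller rise of lymphocytes is not excluded. A batch of the 120 and 168 h libraries alone stays open as well. Apart from the lymphocytes, no biological explanation was tested, since the labels do not set these pools apart.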
